A study of Mus musculus with 24 samples.

How the data were processed

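Total cellular RNA of NIH-3T3 mouse fibroblasts was measured on 24 one-colour Affymetrix expression arrays with one-cycle target labelling, per the labels. The authors summarised the arrays with GCRMA (background correction by probe sequence, normalization between arrays and a summary per probe set), and the deposited values are on the log2 scale. The GCRMA version, and whether all 24 arrays went through a single run, are not stated, so a shift between runs would not be visible here. The range and medians of every array were checked against the log2 scale, and no further transformation or normalization was applied. Raw intensity files were not used here.

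The table held 45101 probe sets, of which 64 controls were left out. Of the other 45037, the GEO platform annotation, which is older than current gene names, gave 34945 a single gene symbol, 932 several and 9160 none. Genes were named only from probe sets with a single symbol, so list members with none, such as Isg15 and Gapdh, have no value. Probe sets were kept with a value above log2 4 on at least 3 arrays, which left 19305 (16890 with a single gene, 521 with several, 1894 with none) covering 9421 genes, 4439 of them by 2 or more probe sets. Where the mean of the lower group was below log2 4, a fold is given as the higher group's mean over that of the lower group with each array below 4 raised to 4. All arrays of the lower group were below 4 there except for Irf2 and Psmb9 (2 of 3 mock arrays at 3 h) and Nod1 (3 of 4 at 1 h). A gene's value is that of its probe set with the highest mean over the 24 arrays. A GRCm38 gene table was used for the order of genes along chromosomes.

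The 7 groups (mock, IFN-alpha and IFN-gamma at 1 h with 4 arrays each, the same at 3 h with 3 each, and mock at 1 h without 4sU with 3) were fitted together with limma 3.58.1 (lmFit and eBayes, R 4.3.3, with the data.table package at version 1.17.8) with a mean per group, no replicate term and 17 residual degrees of freedom. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 19305. The comparisons, 10 in all, were each interferon against mock and against the other at each time, the change of each response between the times, 4sU against none in mock cells, and mock 3 h against mock 1 h. That between the mock times is described only, since time, 4sU dose and labelling window changed together. The p-values measure the spread between these arrays, which may be technical, since the labels do not say whether replicates are separate cultures. These choices, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

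Gene lists, 19 in all, were written from textbook knowledge and share some genes: antiviral effectors, p47 and p65 GTPases, immediate IFN-gamma targets, MHC class I presentation, MHC class II presentation, receptor and JAK-STAT components, interferon regulatory factors, chemokines and cytokines, NF-kB targets, cell death and nuclear body genes, serum immediate early genes, p53 targets, integrated and endoplasmic reticulum stress, heat shock and oxidative stress, cell cycle, fibroblast and matrix, housekeeping, leukocyte markers, and epithelial and endothelial markers. They were tested with camera in limma at a preset correlation of 0.01, adjusted over lists and comparisons together, and again with an estimated correlation. MHC class II presentation and leukocyte markers had 1 measured gene each (Ifi30 and Cd14) and epithelial and endothelial markers 0, so these 3 lists were not tested. Of 96 list tests 39 passed, and 35 with an estimated correlation. Camera values below are from the preset unless stated, which takes list genes as nearly independent. The adjusted p-values of passing lists were larger with the estimated correlation. For antiviral effectors with IFN-alpha at 3 h camera gave 2.67e-09 in place of 4.26e-278, and for GTPases at 1 h 2.26e-05 in place of 1.28e-54.

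Named genes were chosen by rule. For each comparison with mock, for 4sU and for the mock times these were the 15 rising and 8 falling called genes with the largest change among those whose arrays do not overlap between the groups, up to 4 members of each list with the largest change, and a fixed set of 23 genes where measured. For the direct and time comparisons they were the 8 largest called differences in each direction and the fixed set. A result for an item withheld from this text is not reported here. Every gene given as a leading rise or fall therefore lay on 1 side of the other group on all arrays.

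Whether replicate numbers pair the arrays was checked by correlating deviations from the group means. Between the mock, IFN-alpha and IFN-gamma groups of a time every same-numbered pair correlated above 0.1 (1 h: 0.465 to 0.914; 3 h: 0.128 to 0.646), so these comparisons are also given with the replicate number as a block where that changes a call or moves a count. At 1 h 4 of 4 arrays correlated best with their own number for each pair of these groups. At 3 h this was 3 of 3 for mock with IFN-alpha, but 2 of 3 for both pairs of groups with IFN-gamma. The pairing is read from the data, as the labels do not say what a number shares.

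Alternatives were no filter, a filter of log2 above 6, values below 4 set to 4, a 2-fold minimum, quantile normalization again, array medians set equal, array weights, eBayes with trend and robust, only the groups compared, probe sets without the _x_at, _s_at and _a_at types, 1 probe set per gene, the replicate block, mock without 4sU as control, and each array left out in turn. After the data were seen, 3 more were added: without the 1 h arrays of low 5′ actin signal, the actin 3′ minus 5′ difference as a covariate, and without the 3 h arrays numbered 3.

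The pipeline was tested on simulated data with 200 changed probe sets of 19305. With 4 arrays per group it recovered 66 of 100 at a log2 change of 1 and 92 of 100 at 2, with 5 false among 163 calls. With 3 per group it recovered 47 and 81 of 100, with 9 false among 137. The simulated arrays were independent, with 1 spread per probe set at both times. They lacked the shared deviations of same-numbered arrays and the narrower spread of the real 3 h arrays. These rates therefore need not hold for the real data. Plots were drawn with matplotlib 3.10.9, numpy 2.4.6 and Python 3.11.15.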

Results

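Expression of total cellular RNA was measured in NIH-3T3 cells, a mouse embryonic fibroblast line, at 2 times after fresh medium with or without interferon was added. The 24 one-colour arrays formed 7 groups. At 1 h there were 4 arrays each of cells given medium alone (mock), IFN-alpha or IFN-gamma (each at 100 U/ml), all with 4-thiouridine (4sU), a nucleoside that is built into new RNA, at 200 uM for the whole 60 min. At 3 h there were 3 arrays each of the same treatments, with 500 uM 4sU from 150 to 180 min. A further 3 arrays held mock cells at 1 h without 4sU. Values were GCRMA signals on the log2 scale with array medians between 2.95 and 3.11 and between 16933 and 17688 probe sets above log2 4 on each array. Differences below are log2 differences between group means with their standard errors (SE), and the number of arrays limits their precision. Where the mean of the lower group lay below log2 4, taken as background, the fold is a lower bound against that level, written "at least". The log2 difference beside it is of the GCRMA values as given. Fibroblast and matrix genes were abundant (median of gene means 11.97 over 17 genes, highest Vim at 13.8), while leukocyte markers (median 2.46 over 11 genes, highest Cd14 at 5.35) and epithelial and endothelial markers (median 2.53 over 11 genes, highest Epcam at 3.46) lay near background.

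Array quality differed at 1 h. The 3′ probe set of beta-actin exceeded its 5′ probe set by 2.99, 3.09 and 3.43 in replicate 2 of the mock, IFN-alpha and IFN-gamma groups, and by 2.22 and 3.31 in replicates 2 and 3 of the mock cells without 4sU. On the other 1 h arrays and on all 9 arrays of 3 h it lay between 0.78 and 1.37. The median SD of a probe set across replicates was 0.35 to 0.40 in the 1 h groups and 0.12 to 0.13 in the 3 h groups. In the fit all groups share 1 spread per probe set. The SEs and p-values at 3 h therefore carry the wider spread of the 1 h arrays. Those at 1 h in turn carry the narrower spread of the 3 h arrays. The signal of 18S ribosomal RNA was 10.3 in IFN-alpha 3 h replicate 3 and 6.07 in IFN-gamma 3 h replicate 3, against at most 5.71 on any mock array.

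**Figure D1:**
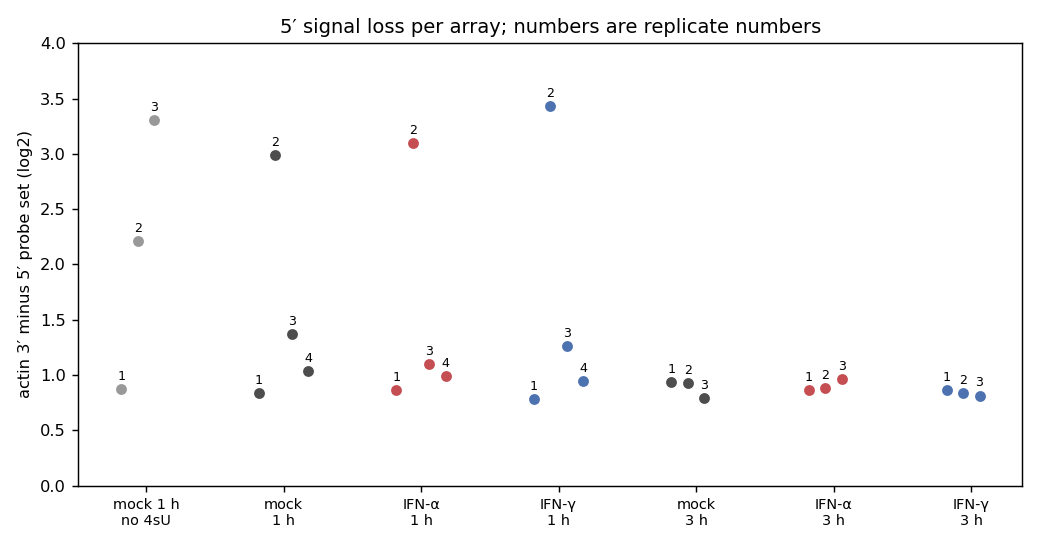
Difference between the 3′ and 5′ probe sets of beta-actin (log2, vertical axis) on each array by group (horizontal axis), 1 point per array with its replicate number. The mock, IFN-alpha and IFN-gamma 1 h arrays numbered 2 sit at 2.99, 3.09 and 3.43, and replicates 2 and 3 of the mock cells without 4sU at 2.22 and 3.31, while the other arrays lie between 0.78 and 1.37.

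The first comparison asked which transcripts responded to IFN-alpha within 1 h. Of the fixed lists, 13 of 36 antiviral effectors, 5 of 11 GTPases and 2 of 6 interferon regulatory factors were higher than in mock cells. Ifit1, whose product binds viral RNA, was 47.1-fold higher (5.56 ± 0.86 SE, n = 4 arrays per group, adjusted p = 0.00188), with 1 mock array, replicate 2, at 7.27 against a mean of 4.27 on the other 3. Cxcl10, which encodes a chemokine for T cells, was 43.1-fold higher (5.43 ± 0.35, adjusted p = 8.25e-09). The transcription factors Irf1 and Irf9 were 10.2-fold (3.35 ± 0.19) and 7.86-fold (2.98 ± 0.25) higher, and Socs3, an inhibitor of cytokine receptor signalling, was 4.33-fold higher (2.12 ± 0.15). For each of these 5 genes every treated array lay above every mock array.

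Of 36 antiviral effectors measured, 13 rose, none fell and 23 did not pass (21 higher adjusted over the list alone; camera adjusted p = 1.27e-97, or 3.59e-06 with an estimated correlation). They included Usp18, which removes ISG15 from proteins (at least 3.93-fold), Ifit3 (12.8-fold) and Rtp4 (11.3-fold). Of 11 interferon-inducible GTPases, which act against intracellular pathogens, 5 rose (8 adjusted over the list alone; camera adjusted p = 1.28e-54), among them Irgm2 (at least 9.86-fold), Igtp (at least 6.80-fold) and Irgm1 (10.8-fold). Of 12 immediate IFN-gamma target genes 3 rose, Cxcl10, Irf1 and Socs3 (5 adjusted over the list alone; camera adjusted p = 6.15e-34). Irf1 and Irf9 were the 2 that rose of 6 interferon regulatory factors (2 adjusted over the list alone; camera adjusted p = 1.63e-17), and Irf9 and Socs3 the 2 of 20 receptor and JAK-STAT components (2 adjusted over the list alone; camera adjusted p = 2.2e-09). Of 15 chemokines and cytokines, Cxcl10 and Il6 (3.99-fold) rose (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000147). Il6 was the only call among 15 NF-kB targets (1 adjusted over the list alone; camera adjusted p = 0.0135; adjusted p = 0.0842 with an estimated correlation). Of 11 cell death and nuclear body genes Trim21 rose (3.40-fold, adjusted p = 0.0444; 2 adjusted over the list alone; camera adjusted p = 2.76e-10). Of 15 genes of MHC class I presentation only Tap1, a peptide transporter subunit, passed (at least 1.54-fold, adjusted p = 0.0436; 1 adjusted over the list alone; camera adjusted p = 0.00181; adjusted p = 0.353 with an estimated correlation). None of 31 serum immediate early genes, 16 p53 targets, 19 stress response genes of the endoplasmic reticulum and integrated pathways, 14 heat shock and oxidative stress genes, 25 cell cycle genes, 17 fibroblast and matrix genes and 12 housekeeping genes passed in limma. The number with an unadjusted p under 0.05 was 1 for the immediate early genes and 0 for the other 6 lists, and adjusted over the list alone there was none. Their camera adjusted p ran from 0.0927 to 1. The median, mean and test of the cell cycle list differed in sign (median 0.03, mean -0.00024, tested up).

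In all, 50 of 19305 probe sets, of 34 named genes, rose with IFN-alpha at 1 h and 0 fell in limma (127 lower at an unadjusted p under 0.05). In both directions 309 had an unadjusted p under 0.05 in limma, fewer than the 965.25 expected by chance, and 974 with the replicate number as a block. Against the mock cells without 4sU the count was 85, 48 higher and 37 lower (45 of the 50 kept, without Mx1). That contrast changes 4sU together with IFN-alpha, and replicates 2 and 3 of its controls had the low 5′ actin signal. Its calls cannot be assigned to IFN-alpha alone. With values below log2 4 set to 4, Iigp1 (adjusted p = 0.111), Oasl2 (0.0885), Mx2 (0.688), Mx1 (0.652) and Tap1 (1) did not pass. With the replicate number as a block, 77 were called (76 higher and 1 lower, 49 of the 50 kept), Bcl3 (adjusted p = 0.00565), Daxx (0.00141), Cd274 (0.0308) and Fos (0.0324) passed as well, and Mx1 moved from 0.0405 to 0.0548. With only the 8 arrays of these groups in the fit the count was 14, Ifit1, Ifit3, Rtp4, Il6, Tap1 and Trim21 being among those that no longer passed. Leaving out a single array ended the calls of Tap1 (mock replicates 1 to 4 and IFN-alpha replicates 1 and 4, adjusted p from 0.0548 to 0.26), Trim21 (mock replicates 1, 3 and 4 and IFN-alpha replicates 1, 2 and 4, from 0.081 to 0.266) and Mx1 (mock replicates 1 to 4 and IFN-alpha replicates 1, 2 and 4, from 0.0656 to 0.227).

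IFN-gamma for 1 h raised Irf1, Socs3, Cxcl10 and Cxcl9 among other genes, and lowered 6 named genes. Irf1 was 38.8-fold higher (5.28 ± 0.19 SE, n = 4 arrays per group, adjusted p = 3.6e-13) and Socs3 16.96-fold higher (4.08 ± 0.15, adjusted p = 3.6e-13). Cxcl10 and Cxcl9, chemokines that share a receptor on T cells, were 22.8-fold (4.51 ± 0.35) and at least 5.69-fold (4.06 ± 0.42) higher. Hoxd3os1, a non-coding transcript of the Hoxd cluster, was 9.59-fold higher (3.26 ± 0.18), the activin antagonist Fst 5.27-fold (2.40 ± 0.26), and the kinase Map3k8 4.32-fold (2.11 ± 0.18). Of the genes that were lower, the phosphatase Dusp1 fell by 1.58 on the log2 scale (± 0.29, adjusted p = 0.00656), the cytokine Lif by 1.51 (± 0.15, adjusted p = 1.84e-06), Mycn by 1.35 (± 0.25) and the homeobox factor Dlx2 by 1.04 (± 0.19).

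GTPases and immediate IFN-gamma targets were raised as groups at 1 h. Of 11 GTPases 5 rose (9 adjusted over the list alone; camera adjusted p = 1.22e-59), with Irgm2 at least 15.6-fold, Igtp at least 11.7-fold, Irgm1 17.9-fold and Iigp1 at least 7.86-fold higher. Of 12 immediate IFN-gamma targets 5 rose and 7 did not pass (9 adjusted over the list alone; camera adjusted p = 1.39e-59): Irf1, Socs3, Cxcl9, Cxcl10 and Cish, a SOCS-family inhibitor. Irf1 and Irf9 (5.62-fold) rose of 6 interferon regulatory factors (2 adjusted over the list alone; median -0.103, mean 1.195, tested up, camera adjusted p = 1.04e-10), and Irf9 and Socs3 of 20 JAK-STAT components (2 adjusted over the list alone; camera adjusted p = 5.29e-11). Of 15 chemokines and cytokines 3 rose, Cxcl10, Cxcl9 and Il6 (3.25-fold), and Lif fell (3 and 1 adjusted over the list alone; camera adjusted p = 5e-06). Il6 and Tnfaip2 (3.41-fold) rose of 15 NF-kB targets (3 adjusted over the list alone; camera adjusted p = 3.98e-08). Of 36 antiviral effectors none passed in limma (3 higher at an unadjusted p under 0.05; 1 adjusted over the list alone; camera adjusted p = 6.86e-05; adjusted p = 0.323 with an estimated correlation). The differences of Ifit1 and Ifit3 were -0.15 and -0.06, and Usp18 lay below log2 4 in both groups (2.27, and 2.24 in mock cells). Tap1 alone of 15 MHC class I genes rose (at least 2.75-fold; 2 adjusted over the list alone; camera adjusted p = 0.00107; adjusted p = 0.323 with an estimated correlation). None of 11 cell death and nuclear body genes passed in limma (3 at an unadjusted p under 0.05), although 3 did so adjusted over the list alone (camera adjusted p = 1.27e-05). Dusp1 was the only call of 31 serum immediate early genes (1 lower adjusted over the list alone; camera adjusted p = 0.21). None passed in limma of 16 p53 targets, 19 stress response genes, 14 heat shock and oxidative stress genes, 25 cell cycle, 17 fibroblast and matrix and 12 housekeeping genes, nor adjusted over the list alone. The counts at an unadjusted p under 0.05 were 1 for the p53 targets, 2 for the stress response genes and 0 for the other 4 lists. Camera adjusted p was between 0.37 and 0.868, and signs differed for heat shock (median -0.07, mean 0.0033, tested up) and housekeeping genes (median -0.0058, mean -0.02, tested up).

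In all, 95 probe sets passed with IFN-gamma at 1 h, 84 higher and 11 lower, of 45 and 6 named genes. Against the mock cells without 4sU the count was 180, 80 higher and 100 lower (76 of the 95 kept, without Arhgef39). Here too 4sU changes together with the interferon, and replicates 2 and 3 of the controls had the low 5′ actin signal. These calls cannot be assigned to IFN-gamma alone. With the replicate block the count was 206 (155 higher and 51 lower, all 95 kept), and Bcl3 (adjusted p = 5.88e-06), Zfp36 (0.00149), Trim25 (0.00197), Fas (0.00295), Psmb9 (0.0175), Casp4 (0.0201), Sod2 (0.0387) and Gbp2 (0.0497) passed as well. With only the 8 arrays of these groups the count was 28, and Mycn, Dlx2, Dusp1, Il6, Tnfaip2 and Tap1 did not pass; another probe set of Cblb, an E3 ubiquitin ligase 5.67-fold higher here, gave -0.11 (adjusted p = 1). Of the remaining lower genes, Ptger4 (-0.84, adjusted p = 0.0253) lost its call without mock replicate 2, 3 or 4 or IFN-gamma replicate 1 or 3 (0.0641 to 0.141), and Arhgef39 (-0.50, 0.0417) without any mock replicate or IFN-gamma replicate 2 or 3 (0.0832 to 0.174). Arhgef39 lay below log2 4 in both groups. With values below 4 set to 4 neither it (adjusted p = 1) nor Tap1 (0.137) passed.

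**Figure D2:**
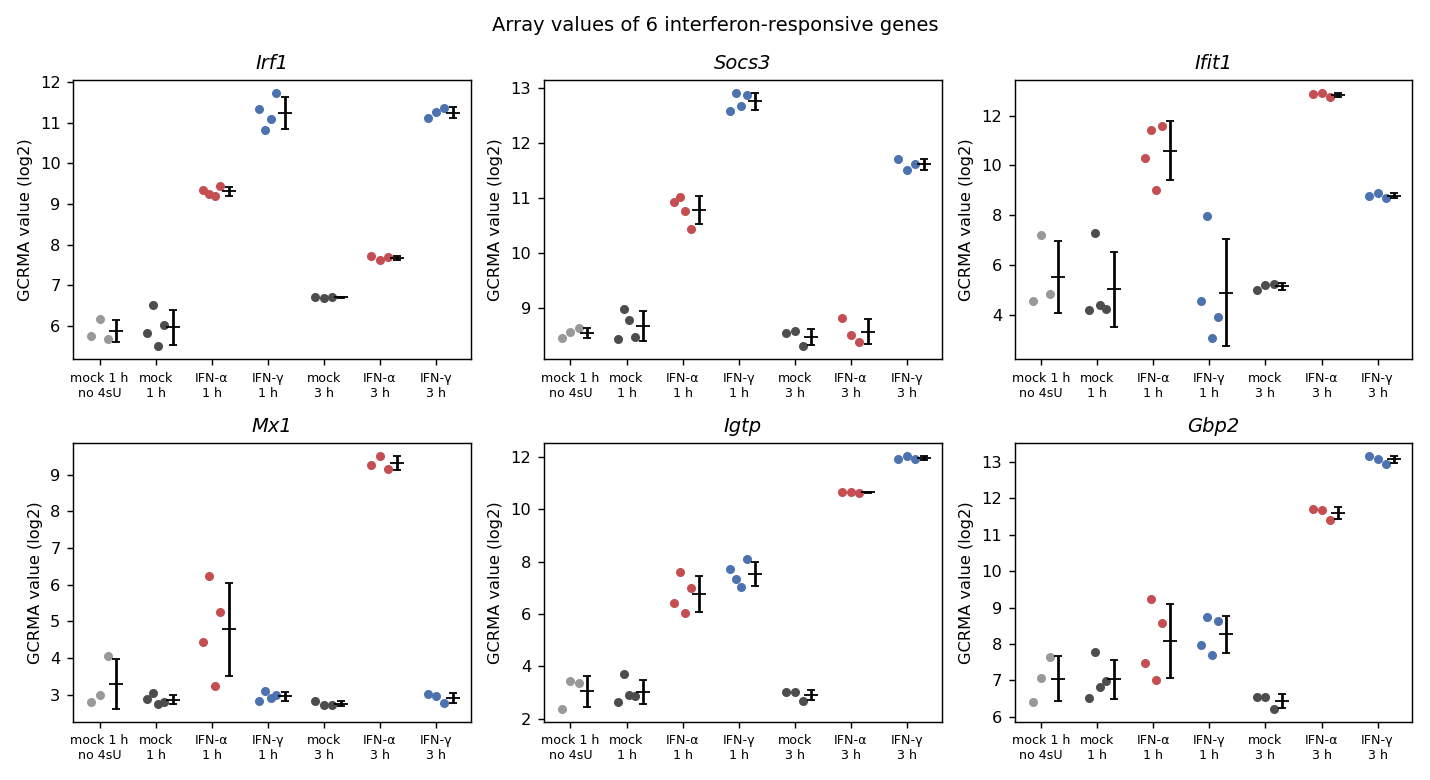
GCRMA values (log2, vertical axes) of 6 genes on each array by group (horizontal axes), with 1 point per array and bars for the group mean ± SD. Irf1 and Socs3 were higher after 1 h of either interferon, Mx1 was at least 39.6-fold higher with IFN-alpha at 3 h and below log2 4 in the mock and IFN-gamma groups of that time, and Igtp and Gbp2 were higher with both at 3 h.

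After 3 h of IFN-alpha the antiviral list had risen almost completely. Cxcl10 was 418-fold higher than in mock cells (8.71 ± 0.40 SE, n = 3 arrays per group, adjusted p = 1.62e-12), Usp18 at least 194-fold (8.48 ± 0.36, adjusted p = 3.64e-13) and Rsad2, which makes an inhibitor of viral RNA synthesis, at least 65.6-fold (7.56 ± 0.72, adjusted p = 2.12e-07). Mx1, a GTPase that restricts influenza virus, was at least 39.6-fold higher (6.55 ± 0.46), Slfn8 at least 54.0-fold (6.60 ± 0.32) and Oasl2 at least 119-fold (7.92 ± 0.43). Irf7, a transcription factor that amplifies interferon production, was at least 6.62-fold higher (4.28 ± 0.19), while Irf1 was 1.97-fold higher (0.98 ± 0.22, adjusted p = 0.021). Of the 5 named genes that were lower, Zfp40 fell by 0.90 on the log2 scale (± 0.15, adjusted p = 0.000583), to below log2 4. With values below 4 set to 4 it did not pass (adjusted p = 0.34).

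Of 36 antiviral effectors 35 rose and none fell, Ifi27l2a being the exception at 1.06 (adjusted p = 0.494; 36 higher adjusted over the list alone; camera adjusted p = 4.26e-278, or 2.67e-09 with an estimated correlation). Of 11 GTPases 10 rose (10 adjusted over the list alone; camera adjusted p = 7.5e-98), such as Iigp1 (at least 125-fold), Igtp (at least 100-fold) and Irgm2 (at least 119-fold). Of 11 cell death and nuclear body genes 8 rose (8 adjusted over the list alone; camera adjusted p = 1.44e-40), including the nuclear body component Sp100 (at least 7.33-fold), Phf11d (at least 25.5-fold) and Daxx (9.24-fold). Of 15 MHC class I genes 3 rose, Tap1 (at least 14.92-fold), the immunoproteasome subunit Psmb9 (at least 10.4-fold) and Tapbp (7 adjusted over the list alone; camera adjusted p = 8.71e-18). Of 6 interferon regulatory factors 4 rose, Irf7, Irf9 (14.3-fold), Irf2 (at least 2.36-fold) and Irf1 (4 adjusted over the list alone; camera adjusted p = 3.26e-17). Of 20 JAK-STAT components 3 rose, Stat2 (21.1-fold), Irf9 and Socs2 (at least 1.45-fold; adjusted p = 0.0645 with values below log2 4 set to 4) (3 adjusted over the list alone; camera adjusted p = 6.32e-05). Of 12 immediate IFN-gamma targets 4 rose, Cxcl10, Cd274 (at least 3.03-fold), Nlrc5 (at least 1.87-fold) and Irf1 (6 adjusted over the list alone; camera adjusted p = 1.91e-18). Of 15 chemokines and cytokines 4 rose, Cxcl10, Il15 (5.67-fold), Ccl2 (4.84-fold) and Il6 (6 adjusted over the list alone; camera adjusted p = 5.93e-09), and of 15 NF-kB targets 2 rose, Ccl2 and Il6 (2.94-fold) (3 adjusted over the list alone; camera adjusted p = 0.00254). Fas, a death receptor, was the only call of 16 p53 targets (2.10-fold; 1 adjusted over the list alone; median -0.06, mean -0.01, tested up, camera adjusted p = 0.883). None of 31 serum immediate early, 19 stress response, 14 heat shock and oxidative stress, 25 cell cycle, 17 fibroblast and matrix and 12 housekeeping genes passed in limma, and 0 had an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p from 0.278 to 0.913). The fibroblast and matrix list had a median of -0.0012 and a mean of -0.02 but tested up.

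In all, 300 probe sets passed with IFN-alpha at 3 h, 295 higher and 5 lower, of 185 and 5 named genes. With the replicate block the count was 408 (398 higher and 10 lower, 299 of the 300 kept), and Psmb10 (adjusted p = 0.000642), Tap2 (0.000757), Vcam1 (0.00209), B2m (0.00337) and Ccl7 (0.0154) passed as well. Without any 1 of the 6 arrays of these groups the calls of Irf1 (adjusted p from 0.0683 to 0.098), Irf2 (0.0544 to 0.122) and Ccl2 (0.128 to 0.142) ended, as did that of Fas without mock replicate 1 or 3 or IFN-alpha replicate 1 (0.0687 to 0.0856). The SDs of Irf1 (0.0104 in mock cells, 0.0495 with IFN-alpha) and Ccl2 (0.0312 and 0.0157) at 3 h were small. Those of the 1 h groups, which enter the same SEs, were 0.114 to 0.427 for Irf1 and 0.823 to 1.03 for Ccl2. Array weights gave 1615 calls and a fit to the 6 arrays alone 506.

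IFN-gamma for 3 h raised 224 named genes and lowered 20. Iigp1 was at least 320-fold higher than in mock cells (9.41 ± 0.52 SE, n = 3 arrays per group, adjusted p = 6.36e-11), Igtp at least 251-fold (9.07 ± 0.35, adjusted p = 1.77e-13), Gbp6 at least 83.6-fold (6.77 ± 0.28) and Gbp2 100-fold (6.64 ± 0.44). Cxcl9 was at least 29.9-fold higher (6.43 ± 0.49), the immune checkpoint ligand Cd274 at least 17.7-fold (5.62 ± 0.30) and Nlrc5, an activator of MHC class I genes, at least 8.26-fold (4.68 ± 0.13). Irf1 remained 23.3-fold above mock (4.54 ± 0.22). Mx1 (2.91, and 2.75 in mock cells) and Rsad2 (2.56 and 2.48) lay below log2 4 in both groups, so a change below background would not be seen. Among the genes that were lower, the vitamin D receptor Vdr fell to 0.435-fold (SE 0.24 on the log2 scale, adjusted p = 0.00476; another probe set adjusted p = 0.343), the neuropeptide receptor Npy1r by 0.87 (± 0.16; -0.45, adjusted p = 0.00141, with values below log2 4 set to 4) and Gprc5b by 0.78 (± 0.15).

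All 11 GTPases rose (11 adjusted over the list alone; camera adjusted p = 7.86e-112). Of 36 antiviral effectors 26 rose and 10 did not pass (28 adjusted over the list alone; camera adjusted p = 1.01e-91), with Oasl2 at least 35.5-fold, Rtp4 42.8-fold and Parp14, an ADP-ribosyltransferase, at least 22.1-fold higher. Of 12 immediate IFN-gamma targets 10 rose (10 adjusted over the list alone; camera adjusted p = 1e-68), among them Socs1 (at least 3.155-fold) and Socs3 (8.79-fold). Of 15 MHC class I genes 6 rose (10 adjusted over the list alone; camera adjusted p = 1.23e-20), including Tap1 (at least 26.7-fold) and Psmb9 (at least 29.35-fold). Of 11 cell death and nuclear body genes 6 rose (6 adjusted over the list alone; camera adjusted p = 9.92e-26), such as Trim21 (at least 16.3-fold) and Fas (4.10-fold). Of 20 JAK-STAT components 5 rose, Stat2 (14.7-fold), Irf9 (10.6-fold), Socs1, Socs3 and Stat3 (7 adjusted over the list alone; camera adjusted p = 9.34e-13). Irf1 and Irf9 rose of 6 interferon regulatory factors (4 adjusted over the list alone; camera adjusted p = 2.38e-12), while Irf7 lay below log2 4 in both groups (2.93, and 2.44 in mock cells). Of 15 chemokines and cytokines 5 rose and Lif fell (7 and 1 adjusted over the list alone; camera adjusted p = 2.54e-10), and of 15 NF-kB targets 4 rose, Tnfaip2 (5.32-fold), Ccl2 (4.85-fold), Cxcl1 (2.17-fold) and Nfkbiz (7 adjusted over the list alone; camera adjusted p = 2.2e-09). Fas was again the only call of 16 p53 targets (1 adjusted over the list alone; median -0.05, mean 0.08, tested up, camera adjusted p = 0.612). None of 31 serum immediate early, 19 stress response, 14 heat shock and oxidative stress, 25 cell cycle, 17 fibroblast and matrix and 12 housekeeping genes passed in limma (5, 1, 2, 0, 0 and 0 with an unadjusted p under 0.05). Adjusted over the list alone, 2 immediate early genes were higher and 1 lower, 1 heat shock and oxidative stress gene was higher and 1 lower, and the other 4 lists had none. Camera adjusted p ran from 0.127 to 0.915, and the stress response list differed in sign (median -0.07, mean 0.00073, tested down).

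In all, 385 probe sets passed with IFN-gamma at 3 h, 363 higher and 22 lower, of 224 and 20 named genes. With the replicate block the count was 657 (545 higher and 112 lower, all 385 kept), and Tap2 (adjusted p = 4.44e-06), Gclm (0.000233), Bcl3 (0.000237), Ifit1 (0.000312, against 0.0683 without the block), Egr2 (0.0025), Jun (0.0033), B2m (0.00374), Ccl7 (0.00398), Atf3 (0.00738), Pdgfrb (0.0149, lower), Zfp36 (0.0229), Hsph1 (0.0353, lower) and Irf2 (0.0392) passed as well. Ccl2 lost its call without any 1 of the 6 arrays (adjusted p from 0.103 to 0.114). Its SD at 3 h was 0.0312 in mock cells and 0.00471 with IFN-gamma. In the 1 h groups, which enter its SE, the SD was 0.823 to 1.03. Array weights gave 2032 calls, a fit to the 6 arrays alone 952, and leaving out the 3 h arrays numbered 3, where Socs1 did not pass (0.181), 242.

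**Figure D3:**
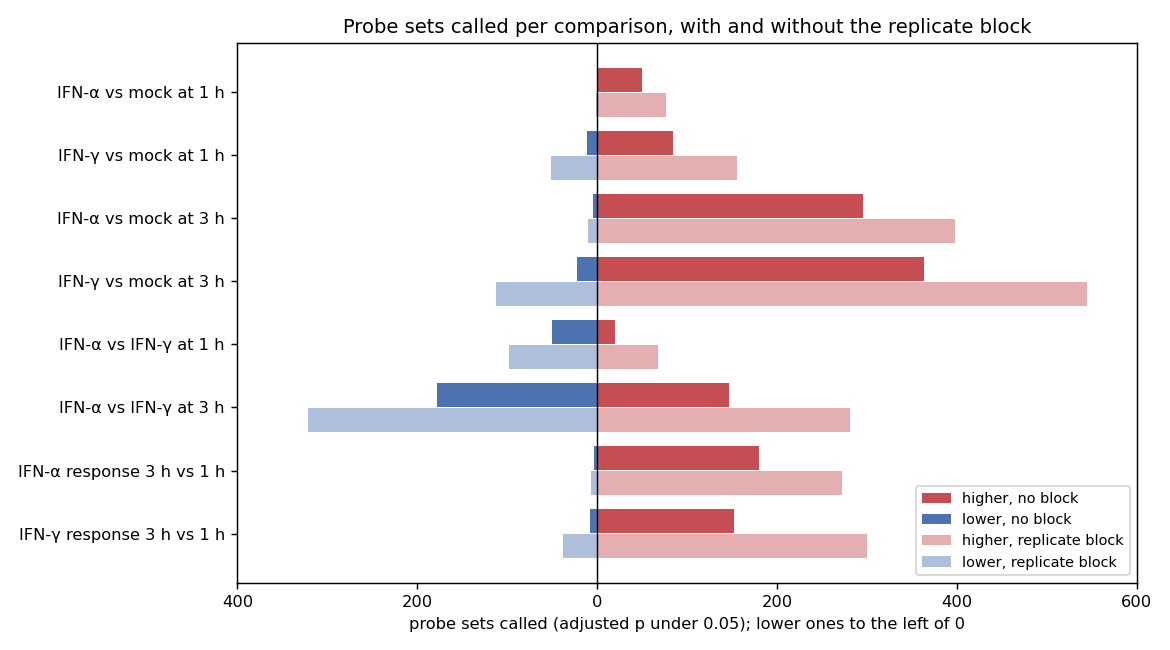
Number of probe sets called at an adjusted p under 0.05 (horizontal axis, higher to the right of 0 and lower to the left) for each interferon comparison, without the replicate block (dark bars) and with it (pale bars). Higher calls outnumber lower ones in each comparison against mock, as with 295 against 5 for IFN-alpha and 363 against 22 for IFN-gamma at 3 h.

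Comparing the treatments directly showed which genes separated the interferons. At 1 h, Ifit1 (5.70 ± 0.86 SE, n = 4 arrays per group, adjusted p = 0.00124), Ifit3 (3.74 ± 0.40), Usp18 (3.70 ± 0.31) and Mx2 (2.26 ± 0.26) were higher with IFN-alpha. Cxcl9 (-3.45 ± 0.42, adjusted p = 8.86e-05), Hoxd3os1 (-2.56 ± 0.18), Socs3 (-1.97 ± 0.15), Fst (-1.94 ± 0.26) and Irf1 (-1.93 ± 0.19) were higher with IFN-gamma. Irgm1 and Igtp, which both interferons raised, differed by -0.73 and -0.78 (adjusted p = 0.57 and 1). Usp18 and Mx2 lay below log2 4 with IFN-gamma and Cxcl9 with IFN-alpha. With values below 4 set to 4 their differences were 1.97, 0.85 (adjusted p = 0.397) and -2.40. Of 70 probe sets that passed, 20 were higher with IFN-alpha and 50 with IFN-gamma. With the replicate block the count was 166 (68 and 98, all 70 kept), and a fit to the 8 arrays alone gave 10, without Ifit1, Ifit3, Mx2 and Cxcl9.

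At 3 h, Rsad2 (7.48 ± 0.72 SE, n = 3 arrays per group, adjusted p = 5.33e-07), Mx1 (6.40 ± 0.46), the nucleotide kinase Cmpk2 (5.74 ± 0.28), Ifit3 (5.36 ± 0.46) and Usp18 (4.64 ± 0.36) were higher with IFN-alpha. So were Ifit1 (4.05 ± 0.99) and Oasl2 (1.75 ± 0.43), both at an adjusted p of 0.0372. Without any 1 of the 6 arrays neither passed (0.12 to 0.145 and 0.108 to 0.182). Cxcl9 (-5.04 ± 0.49, adjusted p = 5.33e-07), Fst (-3.82 ± 0.30), BC023105 (-3.58 ± 0.16), Irf1 (-3.56 ± 0.22) and Socs3 (-3.04 ± 0.18) were higher with IFN-gamma. Rsad2, Mx1 and Cmpk2 lay below log2 4 with IFN-gamma and Cxcl9 with IFN-alpha. With values below 4 set to 4 their differences were 6.04, 5.31, 4.95 and -4.88. Stat2 and Irf9 differed by 0.52 ± 0.46 and 0.43 ± 0.29 (adjusted p = 1 for both). Of 325 probe sets that passed, 147 were higher with IFN-alpha and 178 with IFN-gamma, and the replicate block gave 603 (281 and 322, 324 kept), with Cxcl10 (adjusted p = 0.0139), Gbp2 (0.0161), Igtp (0.018) and Irgm1 (0.0367) called as well. Leaving out the 3 h arrays numbered 3 gave 177. A fit to only the groups compared, array weights and the actin covariate raised the count, as given below with the processing settings.

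**Figure D4:**
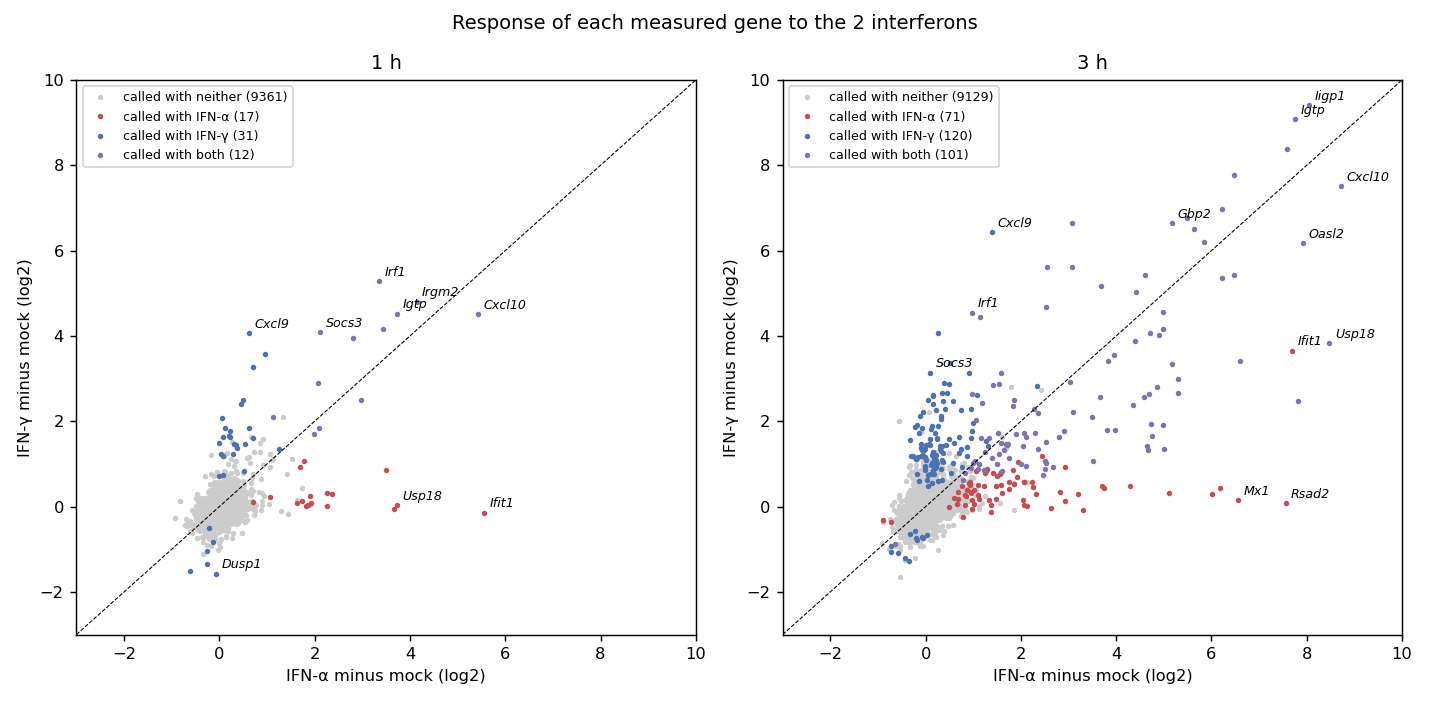
Log2 difference from mock with IFN-alpha (horizontal axis) and with IFN-gamma (vertical axis) for 9421 genes at 1 h and at 3 h, 1 point per gene coloured by which comparison called it, with a dashed line where both are equal. At 3 h, 101 genes were called with both, 71 with IFN-alpha alone and 120 with IFN-gamma alone, and Mx1 and Rsad2, below log2 4 in both the mock and IFN-gamma groups, lie near 0 on the IFN-gamma axis.

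Genes raised by both interferons were more numerous than independent lists would give, with each gene counted here by its probe set of highest mean and above by any probe set. Irf1, Irf9, Socs3, Cxcl10, Il6, Tap1 and 5 GTPases were among the 12 shared at 1 h, out of 29 raised by IFN-alpha and 37 by IFN-gamma (0.114 expected from independent lists). At 3 h 100 were shared of 169 and 208 (3.73 expected). Of the early genes 28 of 29 were called again at 3 h for IFN-alpha, all but Socs3 (0.10 at 3 h, adjusted p = 1), and 31 of 37 for IFN-gamma. Those not called again with IFN-gamma, looked up after their values were seen, included Il6 (0.77 ± 0.30 at 3 h, adjusted p = 0.516), Osgin1 (1.16, 0.107), Sbno2 (1.17, 0.0638), Usp27x (0.50, 1) and Pde4b (-0.01, 1). Both interferons were compared with the same mock arrays, so part of the overlap may come from these. Across the 9421 genes, which are not independent replicates, the differences correlated with r = 0.520 at 1 h (covariance 0.0299, same sign in 64.0%), against 0.501 (0.0142, 66.7%) for simulated unchanged groups. With the mock arrays split between the interferons and treated arrays matched to them by number, the 1 h correlation averaged 0.255 (covariance 0.0197). With all treated arrays it averaged -0.239. In that split the mock arrays of IFN-alpha and those of IFN-gamma deviate from the mock mean equally and in opposite directions. This lowers the correlation by itself, so no conclusion is drawn from -0.239. At 3 h r was 0.724 (covariance 0.172, same sign in 72.3%), against 0.499 (0.0188, 66.7%) simulated, a difference in covariance of 0.154, and 3 mock arrays are too few to split.

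The change of each response with time was tested as an interaction. The IFN-alpha response of Rsad2 grew by 5.66 ± 0.95 (SE, n = 3 or 4 arrays per group, adjusted p = 0.00122), of Oasl2 by 5.54 ± 0.57, of Iigp1 by 5.24 ± 0.69 and of Oas1a, an activator of RNase L, by 4.99 ± 0.15 (adjusted p = 2.34e-15). Oas1a was at background in both 1 h groups (2.23 and 2.24). The other 3 were below log2 4 in mock cells at both times. With values below 4 set to 4 these changes were 4.92, 5.80, 5.15 and 5.00. Irf1 and Socs3 went the other way, with the response lower at 3 h than at 1 h (-2.37 ± 0.30, adjusted p = 2.58e-05, and -2.02 ± 0.23, adjusted p = 8.72e-06). The IFN-gamma response grew for BC023105 (6.25 ± 0.22, adjusted p = 8.6e-14), Gbp6 (6.24 ± 0.37), Ifi47 (5.92 ± 0.53) and Gbp2 (5.41 ± 0.59). BC023105 was below log2 4 in both 1 h groups, and Gbp6 and Ifi47 in mock cells at 3 h. With values below 4 set to 4 the changes of these 3 were 5.06, 6.01 and 5.565. The response of Vdr dropped (-1.75 ± 0.32, adjusted p = 0.00397), although another probe set of Vdr had an adjusted p of 0.238. The change of Irf1 with IFN-gamma was -0.74 ± 0.30 (adjusted p = 0.951).

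For IFN-alpha 184 probe sets passed this test (180 higher and 4 lower at 3 h), and 279 with the replicate block (272 and 7, 183 kept), where Tap1 (2.53, adjusted p = 0.000168) and Fos (-0.91, 0.0266) passed as well. For IFN-gamma 160 passed (152 and 8), and 338 with the block (300 and 38, all 160 kept), where Tap1 (2.53, adjusted p = 0.000218), Ifit3 (2.53, 0.000619) and Ifit1 (3.80, 0.00615) passed as well. Array weights raised both counts and the actin covariate that for IFN-gamma, as given below with the processing settings. The 2 times also differed in 4sU dose and labelling window, which the design does not separate from time.

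Abce1 and Mbnl2 each had a probe set that was lower after 1 h of 4sU. Comparing mock cells with and without it asked whether the label itself alters expression. Of 19305 probe sets 6 were lower with 4sU and 0 higher in limma (314 higher and 1038 lower at an unadjusted p under 0.05, 965.25 expected by chance in both directions together). The 2 with a gene name, chosen after their values were seen, were probe sets of Abce1 (-1.44 ± 0.19 SE, n = 4 and 3 arrays, adjusted p = 0.0035), a ribosome recycling factor, and of the splicing regulator Mbnl2 (-1.42 ± 0.25, adjusted p = 0.04), and for all 6 every labelled array lay below every unlabelled array. The other probe sets of these genes did not pass (Abce1 -0.44 and -0.40, Mbnl2 0.04, 0.51 and 0.32; adjusted p from 0.672 to 0.967). Cdkn1a, the p53-induced inhibitor of cell division, differed by -0.82 ± 0.20 (adjusted p = 0.276), Lif by -0.70 ± 0.16 (0.203) and Klf10 by -0.77 ± 0.19 (0.253). No member of any list passed in limma, and adjusted over the list alone 1 was lower in each of the chemokine, immediate early and p53 lists, these being Lif, Klf10 and Cdkn1a. The p53 list had 3 members lower at an unadjusted p under 0.05, the cell cycle list 4, the immediate early list 1 higher and 1 lower, the antiviral, MHC class I, JAK-STAT, chemokine, NF-kB and stress response lists 1 lower each, and the GTPase, immediate IFN-gamma target, regulatory factor, cell death, heat shock, fibroblast and housekeeping lists 0. Camera adjusted p ran from 0.127 for cell cycle to 0.925 for heat shock. Median, mean and test differed in sign for the antiviral, immediate IFN-gamma target, JAK-STAT, chemokine, NF-kB, cell death, immediate early, p53 and fibroblast lists.

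The count with 4sU depended on single arrays and settings. It was 1 without unlabelled replicate 2, 13 without mock replicate 1 and 3 without mock replicate 4, and 0 with a filter of log2 above 6, with 1 probe set per gene or with the 7 arrays alone. It was 18 with no filter (0 higher), 15 with the actin difference as a covariate (0 higher) and 28 with values below log2 4 set to 4 (1 higher). Array weights gave 3888 (1770 higher and 2118 lower), so neither the number nor the direction holds across settings. Of the unlabelled arrays 2 of 3, and of the labelled ones 1 of 4, had the low 5′ actin signal. Without them 1 unlabelled array, assumed to vary like the other groups, was left against 3 labelled ones. Then 2 probe sets passed, 1 higher and 1 lower, neither among the 6. Abce1 was at -1.05 ± 0.26 (adjusted p = 0.491) and Mbnl2 at -1.50 ± 0.34 (0.458). The mean over the 6 went from -1.68 to -1.62 as its mean SE rose from 0.25 to 0.37.

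Mock cells at 3 h differed widely from mock cells at 1 h, with serum immediate early and inflammatory genes lower. Egr3, an early growth response factor, fell by 3.60 on the log2 scale (± 0.19 SE, n = 3 and 4 arrays, adjusted p = 9.4e-11), the growth factor Hbegf by 3.15 (± 0.32), the NF-kB inhibitor Tnfaip3 by 3.03 (± 0.23; -2.57 with values below log2 4 set to 4) and Lif by 3.01 (± 0.16). Egr1 fell by 0.90 (± 0.13, adjusted p = 0.000129). Sod3, an extracellular superoxide dismutase, was at least 9.87-fold higher (4.33 ± 0.19, adjusted p = 1.27e-11), Car6, a carbonic anhydrase, at least 5.29-fold (3.01 ± 0.19) and Nod1, a sensor of bacterial cell walls, at least 5.62-fold (2.77 ± 0.23).

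Of 31 serum immediate early genes 20 fell and none rose (21 adjusted over the list alone; median -1.27, camera adjusted p = 2.37e-22, or 0.0179 with an estimated correlation; 0 higher at an unadjusted p under 0.05), among them Egr2 (-2.63) and Dusp5 (-2.50). Of 15 NF-kB targets 7 fell and none rose (8 adjusted over the list alone; camera adjusted p = 1.17e-10), and of 15 chemokines and cytokines 6 fell and 1, Il15, rose (6 and 1 adjusted over the list alone; camera adjusted p = 3.53e-05), with Cxcl1 at -2.17, Il6 at -2.09 and Ccl2 at -2.18. Of 36 antiviral effectors 4 rose, Ifi27l2a (8.46-fold), Oas1a (at least 1.42-fold), Bst2 (3.64-fold) and Tor3a, and Ifit2 fell (4 and 2 adjusted over the list alone; median -0.0013, mean 0.24, camera adjusted p = 0.733). Hsph1, a heat shock protein (1.96-fold), was 1 of 2 that rose of 14 heat shock and oxidative stress genes (2 adjusted over the list alone; camera adjusted p = 0.864). Of 25 cell cycle genes 2 rose (2 adjusted over the list alone; camera adjusted p = 0.427). Of 12 housekeeping genes 2 rose (2 adjusted over the list alone; camera adjusted p = 0.201), Pgk1 (0.59 on the log2 scale, adjusted p = 0.0171) and Hprt (1.51-fold, 0.0465). Of 17 fibroblast and matrix genes Postn fell (-1.28; 1 adjusted over the list alone; median 0.13, mean 0.10, tested down, camera adjusted p = 0.913). Of 19 stress response genes Ddit3 rose (1.86-fold; another probe set gave -0.08, adjusted p = 0.886) and Atf3 fell (-1.69, or -1.425 with values below log2 4 set to 4; 2 and 1 adjusted over the list alone; camera adjusted p = 0.717). Of 16 p53 targets Bbc3 fell (-0.96, or -0.61 with values below log2 4 set to 4; 1 lower and 1 higher adjusted over the list alone; median 0.05, mean -0.03, camera adjusted p = 0.746). Of 12 immediate IFN-gamma targets Irf1 rose (1.67-fold) and Cish fell (-0.76; adjusted p = 0.856 with values below log2 4 set to 4; 1 and 1 adjusted over the list alone; camera adjusted p = 0.546), Irf1 was the only call of 6 regulatory factors (1 adjusted over the list alone; camera adjusted p = 0.913), and Mlkl the only call of 11 cell death genes (1.42-fold; none adjusted over the list alone; camera adjusted p = 0.864). None of 11 GTPases, 15 MHC class I genes and 20 JAK-STAT components passed in limma (0, 1 and 5 at an unadjusted p under 0.05; none adjusted over the list alone; camera adjusted p = 0.278, 0.278 and 0.606).

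In all, 2188 probe sets passed between mock 3 h and mock 1 h, 1052 higher and 1136 lower (852 and 1207 after another quantile normalization, 1408 and 969 with array medians set equal). The median difference of all probe sets was 0.06, -0.01 and 0.14 under these 3 scalings. The count was 1301 without mock 1 h replicate 2, and 984, 1034 and 1300 without mock 3 h replicates 1, 2 and 3. Single arrays also ended the calls of Hprt (mock 1 h replicates 2, 3 and 4 and any mock 3 h replicate, adjusted p from 0.0655 to 0.154), Pgk1 (mock 1 h replicate 2 and any mock 3 h replicate, 0.0514 to 0.0679), Irf1 (mock 1 h replicate 3 and any mock 3 h replicate, 0.0751 to 0.0892), Cish (mock 1 h replicates 2 and 3 and any mock 3 h replicate, 0.0741 to 0.161), Mlkl (mock 1 h replicates 2 and 4 and any mock 3 h replicate, 0.0659 to 0.172) and Bbc3 (mock 3 h replicates 1 and 3, 0.0593 and 0.0696). Different probe sets of 14 genes were called in opposite directions. Time, 4sU dose and labelling window changed together, and the actin difference was low on all 3 h arrays but high on mock 1 h replicate 2.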

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

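The tests of the control transcripts in the arrays numbered 2, of shared batches behind the mock times and of immediate early genes were chosen after the results were seen, as was the correction by the actin difference.

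Single arrays stood far from the rest of their group in 9 of 84 tests over 28 measures, and 6 of the 9 were arrays numbered 2. Chance would give about 4.2 if the tests were independent, which they are not. The number and the percent of probe sets above log2 4 are the same quantity. Several flags also fall on the same array, mock 1 h replicate 2, so the 4.2 is only a rough guide. In IFN-alpha 1 h replicate 2 the array median was 3.093 (others 2.989 on average) and the actin 3′ minus 5′ difference 3.095 (others 0.984). In mock 1 h replicate 2 Ifit1 was at 7.273 (others 4.27), Cxcl10 at 5.45 (4.33), Oasl2 at 2.87 (2.40) and Psmb9 at 3.235 (3.40). Fos was at 10.33 in mock 1 h replicate 4 (others 9.26), Oasl2 at 2.481 in IFN-gamma 1 h replicate 1 (2.90), and 18S at 5.084 in IFN-alpha 1 h replicate 4 (4.76). The 18S control signal, which no comparison uses, was 10.28 in IFN-alpha 3 h replicate 3 and 6.072 in IFN-gamma 3 h replicate 3, above the highest mock array at 5.708.

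The labelled 1 h arrays numbered 2 stood apart together. A candidate explanation that stays open is partial RNA degradation or short cDNA, which lowers signal far from the 3′ end. The arrays were singled out with their actin difference, which exceeded that of the others by 2.15 on average, and other control transcripts showed the same: the 3′ minus 5′ difference of Gapdh exceeded that of the others by 0.6399 on average and that of the transferrin receptor by 0.711, each above every other array of its group in all 3 groups. A different cell state with whole transcripts shifted cannot be told apart from it: 2 probe sets of a gene deviated together with r = 0.245 over 4439 genes (0.430 for the difference between the mock times), under the limit of 0.3 set beforehand, but that limit ignored the wider spread of these arrays (SD 0.840, against 0.384 to 0.589 in the others), and their covariance of 0.164 was not below 0.139 for the mock times. No biological explanation is named by the design.

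Mock cells at 3 h and at 1 h differed in 2188 probe sets. RNA quality of the 1 h arrays is argued against as the whole cause, since at least 92.87% of these were called again without the low 5′ actin arrays or with the actin difference as a covariate. The decline of genes induced by fresh medium may account for part: the 31 immediate early genes had a median of -1.267, with 29 below 0, while random lists of that size lay mostly between -0.12 and 0.26 and 0 of 10000 were as low. The random lists used the same contrast in which 20 of the 31 were already called lower, and took the genes as independent. They therefore add no separate support (camera adjusted p = 0.0179 with an estimated correlation). A difference between cultures or array batches of the 2 times cannot be told apart from time, because no group holds arrays of both times, and same-numbered mock arrays of the 2 times did not deviate together (lowest r = -0.2315). No other split of the 7 arrays gave as many calls (1 of 35 splits, the real one, with 1335 for the highest other). That is under 0.05 but the smallest share that 35 splits can give, and the arrays of the 2 times differ in spread. The test thus does not by itself exclude chance for the count, and the design's own differences in time and 4sU stay open.

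The 6 probe sets lower with 4sU could reflect uneven RNA quality, but 98.58% of their mean change was left with the actin difference as a covariate (-1.66, mean SE 0.24, against -1.68, mean SE 0.25), and all 6 were called again, which argues against it as the whole cause. Without the low 5′ actin arrays none of the 6 was called (adjusted p from 0.374 to 0.508), as 1 unlabelled array left a mean SE of 0.37, at a mean change of -1.62. Chance was not excluded for the count, since 4 of 35 splits called as many. The highest other split called 6246 probe sets and set unlabelled replicate 1 with mock replicates 1, 3 and 4 against the 3 arrays of low 5′ actin signal, which points to that structure of the arrays. An effect of 4sU itself stays open.

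The response to IFN-alpha differed between 3 h and 1 h by the test of the difference for 184 probe sets. The named genes, in alphabetical order and with a second value where setting values below log2 4 to 4 changes the first, were Cmpk2 (5.498, or 4.847), Cxcl10 (3.279), Gbp2 (4.11), Gbp6 (5.122, or 4.87), Herc6 (5.219, or 4.431), Ifit1bl1 (5.128, or 4.419), Ifit3 (4.151, or 4.226), Igtp (4.012, or 3.884), Iigp1 (5.244, or 5.147), Irf1 (-2.369), Irgm1 (2.194), Mx1 (4.634, or 4.335), Oas1a (4.99, or 5.002), Oasl2 (5.543, or 5.798), Psmb9 (3.03, or 3.149), Rsad2 (5.656, or 4.919), Socs3 (-2.018), Stat2 (3.299, or 3.947), Usp18 (4.744, or 5.624) and Zfp40 (-0.9134, or -0.274). Zfp40 lost its call without mock 3 h replicate 2 or IFN-alpha 3 h replicate 2 or 3 (adjusted p from 0.0523 to 0.0975), and with values below log2 4 set to 4 (1). Oas1a, Herc6, Ifit1bl1, Cmpk2 and Zfp40 lay below log2 4 in both 1 h groups.

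The response to IFN-gamma differed for 160 probe sets. The named genes, given in the same way, were BC023105 (6.25, or 5.062), Cxcl10 (3.002), Gbp2 (5.408), Gbp3 (5.089, or 5.301), Gbp6 (6.239, or 6.007), Ifi47 (5.919, or 5.565), Igtp (4.552, or 4.425), Iigp1 (5.443, or 5.346), Irgm1 (2.343), Kcnk10 (-0.7322, or -0.6573), Map3k8 (-1.196, or -1.605), Oasl2 (5.885, or 5.149), Parp14 (5.307, or 4.465), Psmb9 (4.156, or 4.354), Stat2 (2.783, or 3.48), Usp18 (3.803, or 2.957) and Vdr (-1.746). BC023105, Usp18, Parp14, Oasl2 and Kcnk10 lay below log2 4 in both 1 h groups. Stat2 lost its call without mock 1 h replicate 1, 3 or 4, IFN-gamma 1 h replicate 3, mock 3 h replicate 1 or 3, or IFN-gamma 3 h replicate 1 or 2 (0.0503 to 0.107). Kcnk10 lost it without mock 1 h replicate 4, IFN-gamma 1 h replicate 1 or 3, mock 3 h replicate 1 or 3, or IFN-gamma 3 h replicate 1 or 3 (0.0531 to 0.14). Map3k8 lost it without mock 1 h replicate 1 or 4, IFN-gamma 1 h replicate 2 or 3, or any mock or IFN-gamma array of 3 h (0.0699 to 0.114).

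Other splits of the arrays were counted for each interferon comparison. At 1 h chance was not excluded by all splits: 2 of 35 reached the real count of 50 for IFN-alpha (highest other 3712), 3 of 35 reached 95 for IFN-gamma (highest other 7163) and 2 of 35 reached 70 for the direct comparison (highest other 2795). Each highest split set replicates 1 and 4 against 2 and 3, many times the real count, which points to structure by replicate number. The splits that part all 4 pairs as the real one does, 8 in number, gave at most 0 other calls in each of the 3, and the blocked counts were 77, 206 and 166. These 8 splits are too few for a share under 0.05, so they do not exclude chance either. At 3 h the 10 splits are too few for a share under 0.05: the real counts were 300, 385 and 325, 1 of 10 splits in each case, and the highest other 0. For the change with time chance was not excluded: 10 of 100 drawn splits reached 184 for IFN-alpha (highest other 273) and 15 of 100 reached 160 for IFN-gamma (highest other 374). Those that did kept the real 3 h groups, and among the remaining splits the highest counts were 3 and 7.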

How the results depend on the processing

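The settings without the low 5′ actin arrays, with the actin covariate and without the 3 h arrays numbered 3 were chosen after seeing the data. Comparisons are given as IFN-alpha and IFN-gamma against mock (1 h, 3 h), their difference, the change of each response, 4sU and the mock times. The cause of each shift was not tested unless the setting tests fewer probe sets or arrays. With only the groups compared, counts were 14 and 28 at 1 h, 506 and 952 at 3 h, 10 and 869 for the difference, 0 for 4sU and 822 for the mock times. For the interferon comparisons this setting no longer shares 1 spread between the times (median SD 0.35 to 0.40 at 1 h, 0.12 to 0.13 at 3 h). The 1 h tests then lose the narrower spread of 3 h, and the 3 h tests the wider spread of 1 h. It also leaves fewer arrays, which was not told apart from this. The 1 h calls of the main fit thus rest in part on the 3 h spread. With 1 probe set per gene, which tests fewer, they were 31, 43, 176 and 228, 39 and 182 for the difference, 111 and 99 for the change of response, 0 and 847. Array weights gave 1615 and 2032 at 3 h, 1977 for the difference at 3 h, 281 and 317 for the change, 3888 for 4sU and 4117 for the mock times. Without _x_at, _s_at and _a_at probe sets IFN-alpha had 29 at 1 h and 122 for the change. Mock without 4sU as control, where 4sU changes together with interferon, gave 85 (48 higher, 37 lower) and 180 (80 and 100) at 1 h. The actin covariate gave 176 for IFN-gamma at 1 h, 129 and 520 for the difference, 295 for the IFN-gamma change, 15 for 4sU and 3901 for the mock times. Without the 3 h arrays numbered 3 there were 242 for IFN-gamma at 3 h, 177 for the difference and 1025 for the mock times. Without the low 5′ actin arrays 4sU had 2 and the mock times 3521. For 4sU no filter gave 18, log2 above 6 gave 0 and values below 4 set to 4 gave 28. For the mock times a 2-fold minimum gave 1032 and log2 above 6 gave 1278.

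With the replicate block counts were 77 and 206 at 1 h, 408 and 657 at 3 h, 166 and 603 for the difference, and 279 and 338 for the change; it changed no other call of a named gene in the interferon comparisons than those given with them. In the other groups not every same-numbered pair correlated above 0.1, the limit used for pairing. The block gave 111 for 4sU (24 higher, 87 lower), where r ran from 0.0809 to 0.802. There 2 of 3 arrays correlated best with their own number, and unlabelled replicate 3 correlated with mock replicate 2 (0.787). For the mock times it gave 5573 (2 of 3, r from -0.232 to 0.127). The pairs of groups with IFN-gamma at 3 h, treated as paired, also had only 2 of 3 best with their own number. Their lowest r was 0.128 with mock and 0.297 with IFN-alpha, so the pairing there is weak.

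With each array left out in turn, counts ran from 38 to 63 and 76 to 99 at 1 h, 250 to 255 and 297 to 314 at 3 h, 51 to 82 and 234 to 242 for the difference, 161 to 188 and 127 to 170 for the change, 1 to 13 for 4sU and 984 to 2675 for the mock times.

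Of 239 calls of named genes none reversed outside the other probe sets. Lost were 45 with only the groups compared, 22 with no filter, 16 with values below 4 set to 4, 15 of 238 with quantile normalization, 4 with equal medians, 4 with array weights, 3 with 1 probe set per gene, 2 with trend and robust eBayes and 1 with the block, 2 of 218 with log2 above 6, 2 of 42 with mock without 4sU as control and 40 of 181 without the 3 h arrays numbered 3. Without the low 5′ actin arrays 7 of 139 were lost: Mx1 with IFN-alpha at 1 h, Mx1 and Oasl2 in the 1 h difference, Arhgef39 and Dlx2 with IFN-gamma at 1 h, and Hprt and Mlkl between the mock times. Of 1890 pairs of a call and a left-out array 211 lost the call. Another probe set of the gene lost 19 of 83 and reversed 3: Cblb with IFN-gamma at 1 h (-0.107) and in the difference (0.137), and Ddit3 between the mock times (-0.085). Of the list tests 39 passed, and between 35 and 51 under the alternatives; the immediate early list reversed for 4sU under the block (-0.150). The correlation of both 1 h responses, 0.52, was 0.255 with the mock arrays split by number. The -0.239 with all treated arrays is lowered by the split itself, as given above, and no conclusion is drawn from it. Low signal limits what arrays show: 25732 probe sets below the filter were not tested.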

Other observations

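The test of genes lower with IFN-gamma was chosen after the result was seen, and the test of neighbouring genes before.

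Genes raised at 3 h lay beside each other in the chromosomal order of measured genes. This order leaves out genes that failed the filter, so such genes may lie between the neighbours. Genes low in mock cells passed the filter only where they were raised, which the random sets do not model. Among 277 genes raised by either interferon there were 52 pairs of neighbours in the order of measured genes, against a mean of 8.16 and at most 22 in random sets of that size (permutation p = 0.0001, the smallest it can give). With pairs of related names left out 29 remained, against a mean of 7.95. Runs of at least 3 numbered 11 and included the guanylate-binding proteins Gbp7, Gbp3, Gbp2b and Gbp2, the Ifit genes Ifit2, Ifit3, Ifit1bl1 and Ifit1, the oligoadenylate synthetases Oas2, Oas1b and Oas1a, and Parp14, Dtx3l and Parp9, whose products act in ADP-ribosylation and ubiquitination. Other runs were Hoxd8, Hoxd3os1 and Hoxd3 with Gm38462, and Tor1aip1, Tor1aip2, Abl2 and Tor3a. The 52 pairs are consistent with members of a genomic cluster being raised together, as a hypothesis, and probe sets that bind several related transcripts were not excluded for the families.

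The 6 genes lower with IFN-gamma at 1 h included 4 that were also lower in mock cells at 3 h than at 1 h without 4sU. Measured against the separate unlabelled 1 h mock arrays, their median difference was -2.069, and 0 of 10000 random sets of that size were as low (5th percentile -0.39). Lif differed by -3.70, Dlx2 by -2.68, Ptger4 by -2.66 and Mycn by -1.48, while Dusp1 differed by 0.04 and Arhgef39 by 1.42. This contrast also differs in 4sU, and unlabelled replicates 2 and 3 had the low 5′ actin signal. With 4sU at 1 h Lif (7.94, against 8.63 without), Dlx2 (9.16, 9.57), Ptger4 (10.97, 11.26) and Mycn (7.42, 8.06) were already lower. So was Dusp1 (9.24, 9.49), but not Arhgef39 (3.66, 3.50). Mock 3 h means of Lif, Dlx2, Ptger4 and Mycn (4.93, 6.89, 8.60 and 6.58) lay below both. Whether IFN-gamma lowers short-lived or serum-induced transcripts in general cannot be told apart from a change of these genes alone. Of the 31 serum immediate early genes only Dusp1 fell with IFN-gamma at 1 h (camera adjusted p = 0.21; adjusted p = 0.887 with an estimated correlation and 0.00904 with no filter).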
